A study of Homo sapiens with 7 samples.

How the data were processed

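Gene expression was measured by sequencing total RNA from UM-UC-3, an established human urothelial carcinoma line. The 7 libraries were 3 clones sorted for high aldehyde dehydrogenase (ALDH) activity, 3 clones sorted for low activity, and 1 wild-type culture. The ALDEFLUOR assay used for the sort makes cells fluoresce in proportion to ALDH activity. Each clone gave 1 library, so the clone was the replicate, and all clones came from 1 line.

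The deposited table lists 13872 genes by Ensembl identifier, symbol and strand, in CPM (counts scaled by library size) rounded to 2 decimals. The columns sum to between 967084.9 and 1019855.1 rather than to a common total. The library size behind the scaling was 24999949 or 24999950 reads for ALDH-high clone 10 and ALDH-low clones 1 and 8, and between 24365061 and 25456516 for the other 4 libraries. The reason for this shared size is not given in the sources used here. The submitters' notes name BWA 0.5.9 and the builds hg19 and mm9 without giving the role of each. Column names end in the name of CAGEr, an R package for 5′-end tags of capped RNA. Whether the libraries were of that type, and how reads were assigned to genes, is not stated in the sources used here. Every listed gene had a value of at least 0.52 CPM in some library, so a filter on low values had been applied, and genes outside the table were not analysed here.

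Within each column the values are whole multiples of a single step, the CPM of 1 read, at a tolerance of 0.0051 CPM (the rounding). That step recovered whole reads for 100% of the values. At a stricter tolerance of 0.1 read, 78.71 to 99.81% of the values passed, because in 4 of the 7 columns the step is not a whole number of hundredths and rounding can then exceed 0.1 read. The recovered totals were 24177114 to 25664901 reads in listed genes per library. Of the 13872 listed genes, 1017 share all 7 values with another gene, which leaves the source of their reads uncertain. Such reads may count more than once in the recovered totals, which are therefore not a measure of sequencing depth. The recovery was tested on simulated data, where the step was found in 6 of 6 libraries with 0 wrong read numbers.

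Genes with at least 1 CPM in at least 3 of the 6 clone libraries were tested (12705 genes). ALDH-high was compared with ALDH-low on log2(CPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided). P values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and a gene below it is said to have risen or fallen. Fold changes on this scale are compressed for genes near 0 CPM. For genes with 1 to 3 reads in a group, the ratio of reads is given with its exact 95% counting interval, scaled by library size, and for a group with 0 reads a lower bound against a floor of 3 reads over the group is given. Intervals and floors cover counting error only.

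Before the data were examined, 33 gene lists were fixed, along with the tests, the alternatives below apart from those named as added, and the rule for the genes that the text names. Lists with at least 5 tested members (25 lists) were tested with camera at a preset inter-gene correlation of 0.01, adjusted over these lists, and again with an estimated correlation and with fry. Counts of genes are also given adjusted over the list alone. The rule names GRIK2, ALDH genes, the 15 largest changes in each direction among genes whose groups do not overlap, and the 4 members of each list with the smallest unadjusted p. It also names the 8 genes in each direction whose wild-type value lies farthest outside the 6 clones, and the 4 genes per clone with the largest gap to all other libraries. Some genes that the rule names are not reported here. The remaining ALDH genes are covered by counts, apart from ALDH3A2, which has the highest level among them.

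The wild-type library had no replicate, so it was set beside the clones without a test. For each list, the median difference of wild type from the clone mean was ranked among 10000 random lists matched on expression in 20 bins. Gene order along chromosomes came from GENCODE release 29 (GRCh38), matched by identifier for 96.6% of genes. Since the submitters' notes name hg19, only chromosome names and neighbour order are used. Windows held 50 neighbouring genes with 1 gene kept per set of identical values, and were compared with 1000 shuffled gene orders. In a further fit, the median of 25 neighbours on each side was subtracted from each gene in each library.

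The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at 5 CPM, median-ratio scaling, quantile normalization, eBayes without trend and with robust estimation, library weights, all 7 libraries in the fit, and each clone left out. Added after the data were seen were edgeR 4.0.16 (quasi-likelihood test) and DESeq2 1.42.0 on the recovered reads, 1 gene per set of identical values, and the neighbour subtraction. On simulated data with 200 changed genes, limma found 30.6% of genes changed 2-fold, 87.5% of those changed 4-fold and 100% of those changed 8-fold or 16-fold, with 14 unchanged genes among its calls (8.2%). For edgeR the shares were 26.5%, 89.6%, 100% and 100%, with 10 unchanged genes (6%). The simulation drew each gene independently, without the runs along chromosomes described below. Its shares of unchanged genes among the calls need not hold for the real calls. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.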

Results

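RNA was sequenced from 7 cultures of UM-UC-3, a human line derived from a bladder cancer. There were 3 ALDH-high clones (numbers 1, 6 and 10), which the submitters call stem-like, 3 ALDH-low clones (numbers 1, 3 and 8), called non-stem-like, and 1 wild-type library as control. The clones are separate clones of 1 line, so n = 3 per group counts clones, and the wild type has no replicate. The recovered reads summed to 24177114 to 25664901 over the listed genes per library. In these totals, reads of genes with identical values may count more than once. Since 1 read corresponds to about 0.04 CPM, a count of 0 allows up to 0.118 to 0.123 CPM. Values are CPM as mean ± SD over the 3 clones of a group, and changes are ALDH-high minus ALDH-low on log2(CPM + 1).

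The comparison of ALDH-high with ALDH-low clones asks which genes mark the cells sorted for ALDH activity, GRIK2 among them, since the series title names it as a target for immunotherapy. GRIK2 (ENSG00000164418, chromosome 6), which encodes a kainate-type glutamate receptor subunit, was at 18.6 ± 6.89 CPM in ALDH-high clones and 0.0133 ± 0.0231 CPM in ALDH-low clones (n = 3 each). Its ALDH-high values were 20.07, 11.04 and 24.56 CPM in clones 1, 6 and 10, against 0, 0.04 and 0 CPM in ALDH-low clones 1, 3 and 8, and wild type had 15.79 CPM. The groups held 1388 and 1 reads, a ratio of 1410 with a counting interval of 252 to 55500. GRIK2 rose by 4.20 log2 units (SE 0.296, adjusted p = 0.00103). ALDH1A1 (ENSG00000165092, chromosome 9), an enzyme that oxidises retinaldehyde to retinoic acid, was at 57.3 ± 34.1 against 0.0267 ± 0.0462 CPM. It rose by 5.68 log2 units (SE 0.368, adjusted p = 0.000627), with 4292 against 2 reads, a ratio of 2170 (interval 601 to 17900).

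In all, 170 of 12705 tested genes passed, 82 higher and 88 lower in ALDH-high clones. The groups did not overlap in any of the 170, nor in 3314 tested genes (26.1%), where chance gives 10% for 3 against 3. At an unadjusted p under 0.05 there were 2502 genes. Of the genes that rose, 31 had an ALDH-low mean under 0.5 CPM, and of those that fell, 23 had an ALDH-high mean under 0.5 CPM. Changes exceeded 4 log2 units in 9 genes and were under 1 log2 unit in 29.

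The count of 170 depended on the test and the clones. edgeR passed 129 genes (116 shared with limma), DESeq2 1004 (169 shared), library weights gave 700 and a filter at 5 CPM 86. Without ALDH-high clone 6 or 10 there were 57 or 34, and without ALDH-low clone 1 or 8 there were 44 or 37, while leaving out ALDH-high clone 1 gave 115 and ALDH-low clone 3 gave 173. Only 86 of the 115 and 100 of the 173 were among the 170, so a similar total did not mean the same genes. An exact permutation test of a single gene cannot go below p = 0.1 with 3 against 3, so the calls rest on limma's pooled variance.

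**Figure D1:**
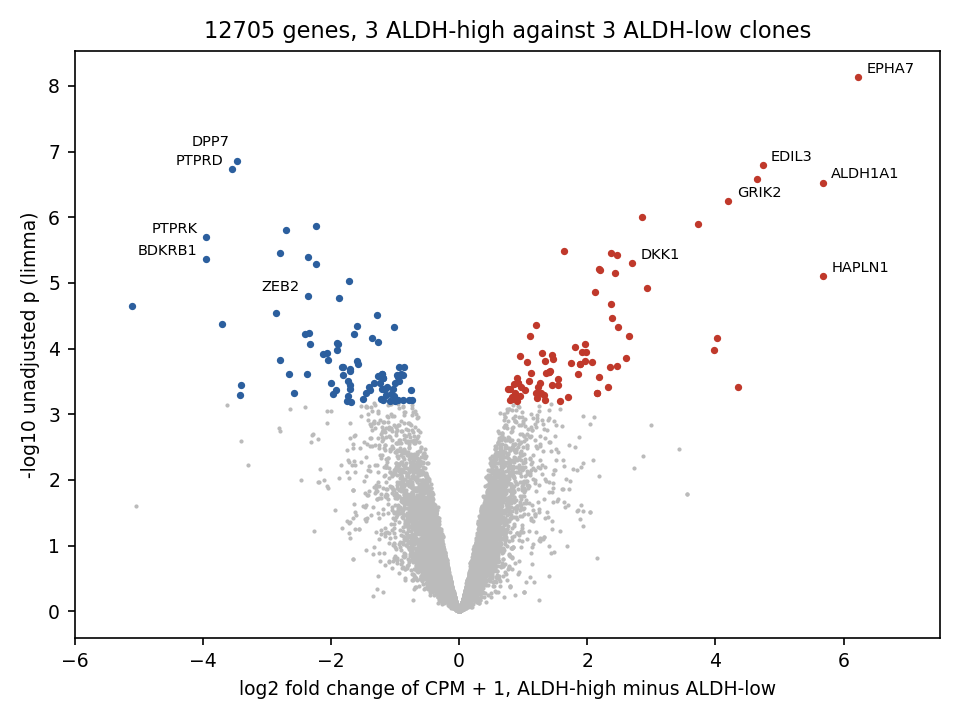
Each point is 1 of 12705 tested genes, with the log2 fold change of CPM + 1 (ALDH-high minus ALDH-low, 3 clones each) on the horizontal axis and minus log10 of limma's unadjusted p on the vertical axis. Red marks the 82 genes that rose, blue the 88 that fell and grey the rest, and EPHA7 at 6.22 log2 units lies farthest to the right.

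The largest rise was that of EPHA7 (ENSG00000135333, chromosome 6), an ephrin receptor tyrosine kinase, from 0.04 to 79.1 ± 24.9 CPM (6.22 log2 units, SE 0.253, adjusted p = 9.41e-05). It had 5914 against 3 reads, a ratio of 2000 (interval 683 to 9680). HAPLN1, a link protein of the hyaluronan matrix on chromosome 5, stood at 66.3 ± 56.3 against 0.0133 CPM (5.68 log2 units, adjusted p = 0.00414). Its values were 128.95, 20.03 and 50 CPM in ALDH-high clones 1, 6 and 10, and without clone 1 it rose by 5.015 log2 units (limma adjusted p = 0.00303). EDIL3, a secreted integrin ligand that is a close neighbour of HAPLN1, was 102-fold higher at 35.3 ± 10.8 CPM (adjusted p = 0.000579). The adhesion receptor gene LPHN3 was 150-fold higher and the receptor phosphatase gene PTPRM 24-fold higher. DKK1, a secreted Wnt antagonist, reached 8.36 ± 1.74 against 0.45 ± 0.301 CPM (adjusted p = 0.00333). PCSK1N, which encodes a proprotein convertase inhibitor, was 54.7-fold higher. RP11-151D14.1, a gene next to ALDH1A1 in the annotation, rose 305-fold, and RORB, a nuclear receptor gene 2 genes beyond ALDH1A1, rose 18.4-fold (adjusted p = 0.0187). Further large rises were those of CPED1, the keratin 8 pseudogene KRT8P3 and TESC, with adjusted p from 0.0188 to 0.0284. All 3 and RORB lost their call with edgeR (adjusted p from 0.0504 to 0.0969) and without ALDH-low clone 1 or 8. So did CPED1 without ALDH-high clone 6, RORB without clone 10, KRT8P3 without clone 1 or 6 and TESC without clone 1 or 10 (adjusted p up to 0.122). Folds over a mean near 0 rest on few reads in single clones, such as RORB with 1.14 CPM in ALDH-low clone 3 and 0.04 in the others, CPED1 with 3.61 there against 0.16 and 0.72, and LPHN3 with 0.28 in ALDH-low clone 1 and 0 in the others.

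The largest fall was that of CTB-60B18.15 on chromosome 19, from 120 ± 42.4 CPM in ALDH-low clones to 3.16 ± 2.895 CPM in ALDH-high clones, a change of -5.11 log2 units (SE 0.585, adjusted p = 0.00917). It lost its call without ALDH-low clone 8 (adjusted p = 0.0852). BDKRB1, a bradykinin receptor gene, stood at 0.547 ± 0.739 against 21.98 ± 6.33 CPM (-3.95 log2 units, adjusted p = 0.0031). The receptor phosphatase genes PTPRK and PTPRD fell 33.8-fold and 214-fold, with adjusted p of 0.00212 and 0.000579. DPP7, a dipeptidyl peptidase gene, was 200-fold lower at 0.0533 ± 0.0231 against 10.64 ± 1.502 CPM. The folds of PTPRD and DPP7 each rest on 4 reads in ALDH-high clones, against 862 and 804, so their size is imprecise. COX7B2, a paralog of a cytochrome c oxidase subunit, had 1 read against 1073, a ratio of 1060 (interval 190 to 41900). The nucleotide-sugar transporter gene SLC35D2 and PRR16 each had 2 reads in ALDH-high clones, with ratios of 215 (interval 59.3 to 1780) and 179 (49.1 to 1480). TENM2, a teneurin gene, had 0 reads in ALDH-high clones against 461, at least 152-fold lower. TNC, which encodes the matrix protein tenascin C, fell 83.2-fold (adjusted p = 0.0445), with 7.88, 37.79 and 5.08 CPM in ALDH-low clones 1, 3 and 8. Its change of -3.42 log2 units was -2.625 without ALDH-low clone 3 (adjusted p = 0.0131). DGKI, C15orf52, SMIM10, the antisense RNA APCDD1L-AS1 and the transporter gene SLC43A3 completed the 15 largest falls, between 9.21-fold and 92.3-fold. The fold of 92.3, that of APCDD1L-AS1, rests on 6 reads in ALDH-high clones. TNC, DGKI and SLC43A3 lost their call when any clone other than ALDH-low clone 3 was left out, and TENM2 when any clone other than ALDH-low clone 8 was left out (adjusted p up to 0.16). SLC43A3 had 18.23 CPM in ALDH-low clone 3 and 5.16 in the others. COX7B2 lost its call without ALDH-high clone 10 or ALDH-low clone 1 or 8 (adjusted p up to 0.0881), C15orf52 without ALDH-low clone 1 or 8 (up to 0.0881), PRR16 without ALDH-high clone 6 or 10 (up to 0.0816) and APCDD1L-AS1 when any ALDH-high clone or ALDH-low clone 8 was left out (up to 0.129). With all clones kept, PRR16, APCDD1L-AS1, TNC, DGKI, TENM2 and SLC43A3 lost theirs with a pseudocount of 5, TNC and SLC43A3 without a filter and with a filter at 5 CPM, TNC with eBayes without trend or with robust estimation, and SLC43A3 with edgeR (up to 0.105). With neighbours subtracted TNC, DGKI and SLC43A3 lost theirs (0.0731, 0.0573 and 0.066).

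**Figure D2:**
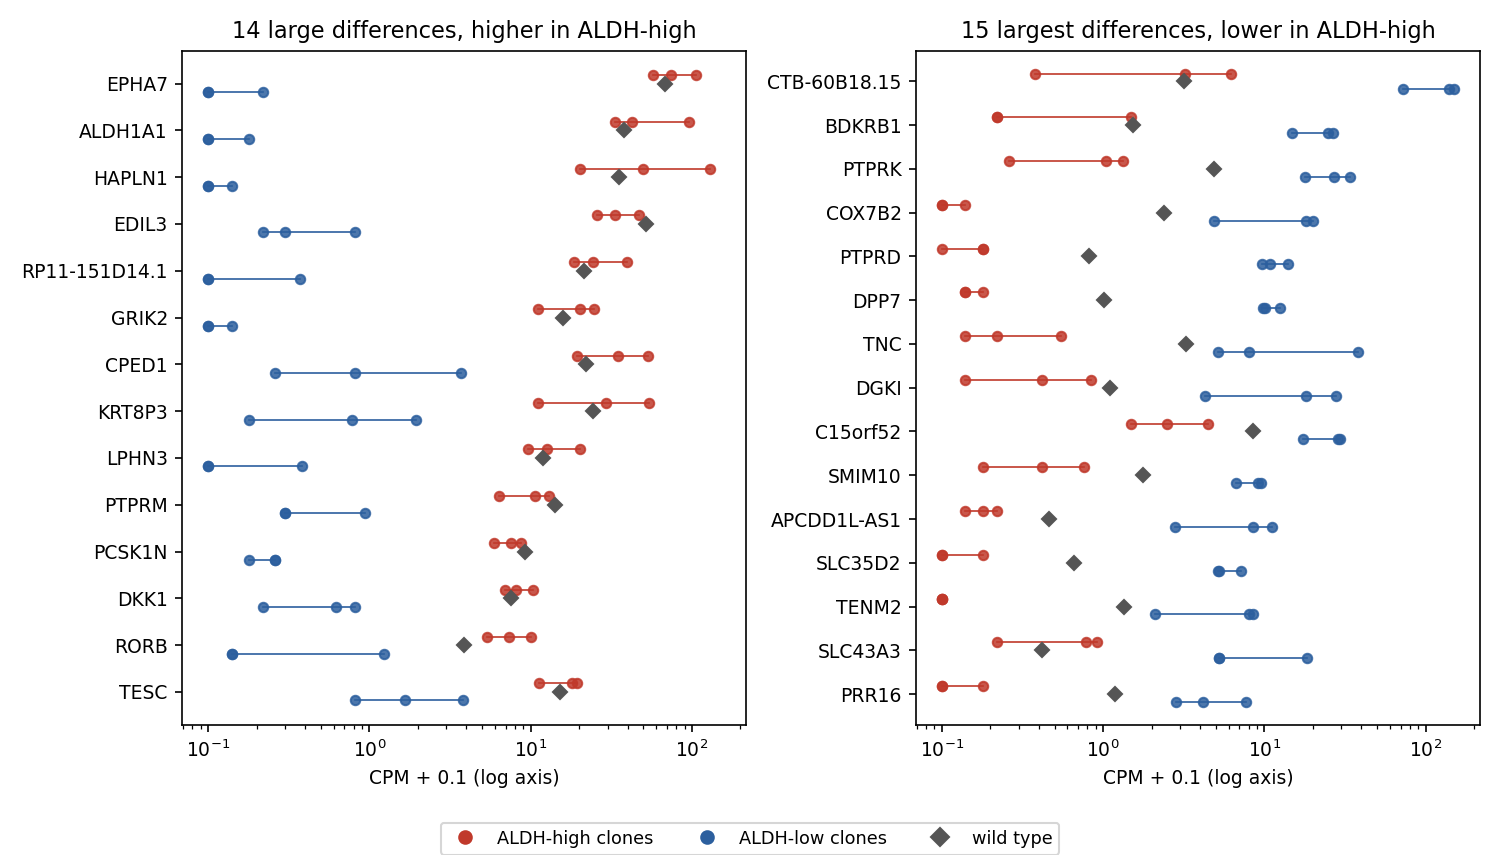
CPM + 0.1 on a log axis for 14 genes with large rises (left) and the 15 genes with the largest falls (right), with 1 point per clone (red ALDH-high, blue ALDH-low), a line over the range of each group and a grey diamond for wild type. The 3 ALDH-high clones and the 3 ALDH-low clones do not overlap for any of the 29 genes, and wild type at 15.79 CPM lies within the ALDH-high range for GRIK2.

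Of the 19 ALDH genes on the list only 11 were in the deposited table, so the others could not be compared. Of the 11 ALDH genes tested, 2 rose, 0 fell and 9 did not pass, and adjusted over the list alone 3 rose and 1 fell. Besides ALDH1A1, ALDH5A1, which encodes succinate semialdehyde dehydrogenase of GABA breakdown, rose from 4.33 ± 0.771 to 13.5 ± 1.99 CPM (1.44 log2 units, SE 0.21, adjusted p = 0.0264). Its call was lost when any clone other than ALDH-low clone 3 was left out (adjusted p up to 0.113). ALDH6A1 at 6.96 against 2.95 CPM and ALDH3B1 at 3.92 against 9.84 CPM passed over the list alone, with adjusted p of 0.0891 and 0.123 over all genes. ALDH3A2, with the highest level of the family, was at 65.35 ± 8.704 against 46.9 ± 11.9 CPM (adjusted p = 0.256). The list's median change was 0.05 and its mean 0.68 log2 units, and camera gave adjusted p = 0.0817. Of the 18 ionotropic glutamate receptor genes 2 were tested, and the others were not in the deposited table. Besides GRIK2 this was GRID1, at 2.90 ± 1.57 against 0.37 ± 0.305 CPM (1.44 log2 units, adjusted p = 0.0933), which passed adjusted over the list alone.

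Camera called 6 of the 25 lists it tested, 3 upward and 3 downward, and none of the 6 passed with an estimated correlation or with fry (smallest adjusted p 0.59 and 0.0781). Of the 10 ways to split the 6 clones into 3 and 3, 9 gave as many called lists or more, the real split included. The number of called lists therefore does not set the ALDH groups apart from other groupings of these clones. The G1/S and DNA replication genes were higher in ALDH-high clones for 29 of 30 members (median 0.39 log2 units, adjusted p = 7.53e-08; adjusted p = 0.59 with an estimated correlation). MCM4, a subunit of the replicative helicase, rose from 161 ± 8.48 to 273 ± 21.4 CPM (0.76 log2 units, adjusted p = 0.0406). MCM7 joined it when adjusted over the list alone, which makes 2 genes, and the other members, SLBP and CDC6 among them, did not pass. Replication-dependent histone genes were higher for 35 of 35 members (median 0.53, adjusted p = 6.17e-11; adjusted p = 0.722 with an estimated correlation). Limma passed 0 histone genes, over all genes or the list alone, with 19 at an unadjusted p under 0.05, and edgeR passed 0 and DESeq2 3. The 4 with the smallest p were HIST1H2BM, HIST2H2AB, HIST1H4A and HIST1H1D, with changes of 0.68 to 0.82 log2 units. Interferon-stimulated genes were higher for 20 of 23 members (median 0.71, adjusted p = 0.000241; adjusted p = 0.722 with an estimated correlation). IFI6, an interferon-induced mitochondrial protein gene, rose from 11.7 ± 3.68 to 48.1 ± 15.2 CPM (1.96 log2 units, adjusted p = 0.0287), and 6 genes rose when adjusted over the list alone, with IFIT2, USP18 and IRF7 at 1.72, 1.19 and 1.64 log2 units. A filter at 5 CPM ended the call of this list (adjusted p = 0.154). The call of MCM4 was lost when any clone other than ALDH-high clone 1 was left out (adjusted p up to 0.168), with a filter at 5 CPM, with eBayes without trend, with edgeR (up to 0.0665) and with neighbours subtracted (0.0668). The call of IFI6 was lost without ALDH-high clone 6 or 10 or ALDH-low clone 1 or 8 (up to 0.112).

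Mesenchymal genes were lower in ALDH-high clones for 14 of 16 members (median -0.84 log2 units, adjusted p = 9.15e-05; adjusted p = 0.59 with an estimated correlation). ZEB2 and SNAI2, transcription factors of epithelial-mesenchymal transition, fell by 2.36 log2 units (0.443 ± 0.301 against 6.403 ± 1.574 CPM, adjusted p = 0.00706) and 1.69 log2 units (0.177 ± 0.203 against 2.94 ± 1.33 CPM, adjusted p = 0.0493). Adjusted over the list alone 5 fell, with MMP2, a matrix metalloproteinase, at 8.22 against 21.5 CPM and the surface glycoprotein gene THY1 at 0, 11.37 and 0 CPM in ALDH-high clones 1, 6 and 10 against 22.1 ± 6.15 CPM. THY1 did not pass over all genes by limma or edgeR (adjusted p = 0.108 and 0.396), and passed without ALDH-high clone 6 (adjusted p = 0.0013). Cholesterol biosynthesis genes were lower for 21 of 22 members (median -0.49, adjusted p = 2.65e-08; adjusted p = 0.59 with an estimated correlation). FDPS, which makes farnesyl diphosphate, fell from 114 ± 12.1 to 61.1 ± 3.78 CPM (-0.88 log2 units, adjusted p = 0.0338). LSS, which makes lanosterol, fell from 60.8 ± 13.5 to 21.9 ± 6.47 CPM (-1.45 log2 units, adjusted p = 0.0427), and adjusted over the list alone 11 fell, FDFT1 among them. Hypoxia response and glycolysis genes were lower for 23 of 28 members (median -0.52, adjusted p = 0.000173; adjusted p = 0.766 with an estimated correlation). Limma passed 0 of them over all genes, with 10 at an unadjusted p under 0.05, edgeR 0 and DESeq2 8, and 4 fell when adjusted over the list alone (HK1, PKM, P4HA2 and GPI). This list stood 0.97 log2 units above the clone mean in ALDH-low clone 1, and its call ended without that clone (adjusted p = 0.138). The calls of SNAI2, FDPS and LSS were lost when any clone other than ALDH-low clone 3 was left out (adjusted p up to 0.174, 0.141 and 0.154). With all clones kept, SNAI2 lost its call with a pseudocount of 5, without a filter, with edgeR (up to 0.0717) and with neighbours subtracted (0.0734). FDPS lost its call with eBayes without trend (0.0543), and LSS with that setting, without a filter and with a filter at 5 CPM (up to 0.055).

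**Figure D3:**
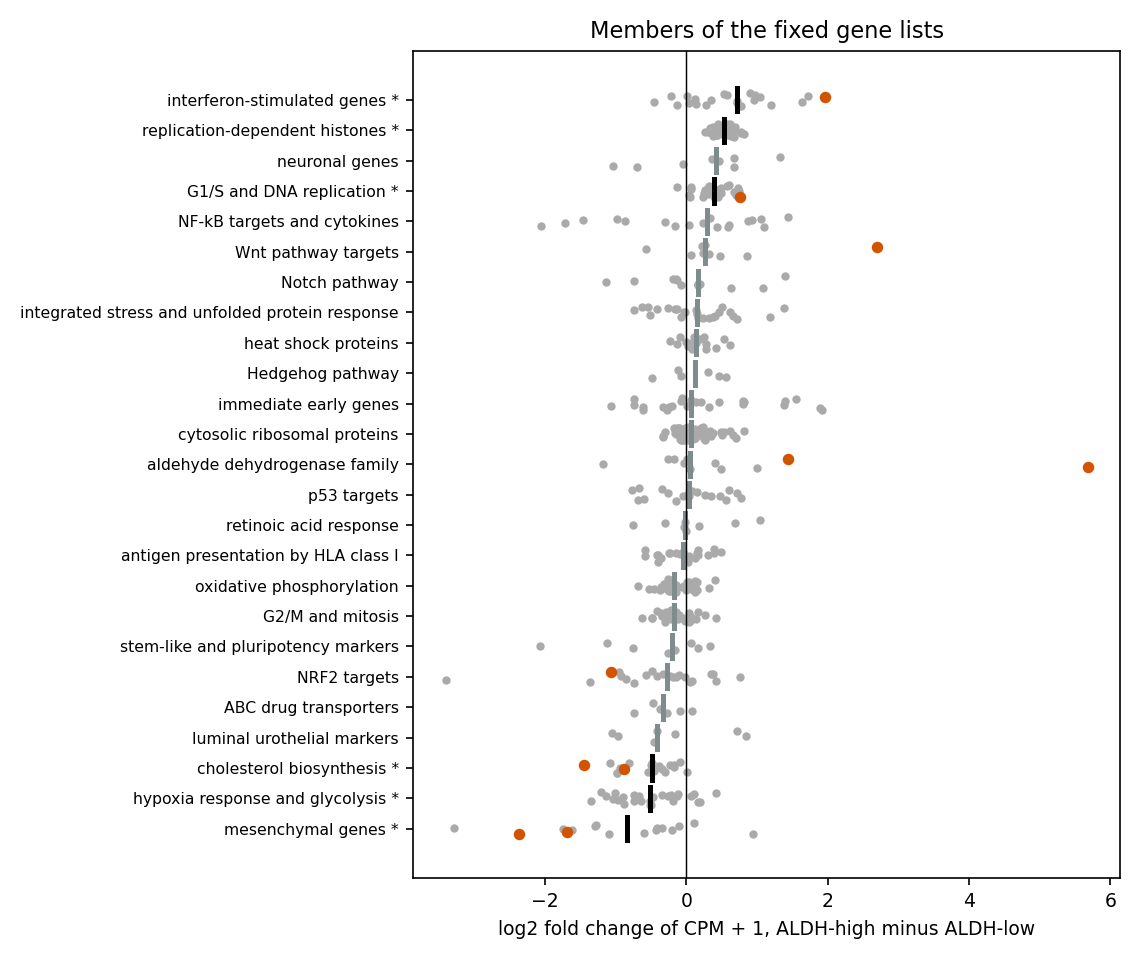
Each point is a tested member of 1 of the 25 lists, at its log2 fold change of CPM + 1 (ALDH-high minus ALDH-low, 3 clones each), and the bar is the list's median. Orange points are genes that passed over all genes, and a star and black bar mark the 6 lists that camera called at its preset correlation, among which the histones lie at a median of 0.53 and the mesenchymal genes at -0.84 log2 units.

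Few markers of stem-like cells and of urothelial type could be tested, and none of these rose or fell by limma. Tested were 8 of 24 stem-like, 7 of 21 luminal, 2 of 20 basal and 4 of 21 junction genes. Since limma found only 30.6% of 2-fold changes in simulated data, a missing call does not show a missing change. Of 8 stem-like and pluripotency markers tested limma passed 0, with 2 at an unadjusted p under 0.05, edgeR 0 and DESeq2 1, and 1 fell when adjusted over the list alone. That was ITGA6, an integrin subunit, at 26.8 ± 14.9 against 108 ± 37.6 CPM (-2.06 log2 units, adjusted p = 0.0553). SOX9 was at 4.27 against 9.98, CD44 at 376 against 587 and BMI1 at 58.25 against 69.2 CPM. The 7 luminal urothelial markers gave 0 calls by limma and edgeR (3 unadjusted, 1 by DESeq2, 0 over the list alone), with KRT8 at 136 against 81.5 CPM, KRT18 at 502 against 302, KRT7 at 1.99 against 5.30 and ERBB2 at 12.5 against 17.4. Of the 2 basal markers tested, EGFR at 18.5 against 38.3 CPM passed over the list alone, and limma, edgeR and DESeq2 gave 0 calls over all genes (1 unadjusted). The 4 epithelial junction genes gave 0 calls by limma, edgeR and DESeq2 (1 unadjusted), with TJP1 at 39.2 against 66.4 and PKP3 at 5.03 against 7.54 CPM. The 6 ABC transporter genes gave 0 calls by all 3 tools (2 unadjusted), with ABCC4 at 21.2 against 29.7 CPM, ABCC3 at 0.79 against 2.15, ABCC1 at 8.71 against 11.4 and ABCC10 at 4.44 against 5.59. The 8 retinoic acid response genes gave 0 calls by limma and edgeR and 2 by DESeq2 (2 unadjusted), with HOXD4 at 11.9 against 20.95 CPM, which passed over the list alone, RDH10 at 12.53 against 5.203, HOXA4 at 2.36 against 3.14 and DHRS3 at 9.82 against 5.45. Their median was -0.01 and their mean 0.10 log2 units.

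Of 21 tested genes of HLA class I presentation limma passed 0 (2 unadjusted, 0 over the list alone), edgeR 0 and DESeq2 1 (B2M), with B2M at 337 ± 42.6 against 505 ± 63.8 CPM, PDIA3 at 163 against 248, TAPBP at 62.1 against 83.8 and HLA-E at 96.6 against 72.7. Of the cancer-testis antigens 3 were tested, with 0 calls by limma, edgeR and DESeq2 and 0 at an unadjusted p under 0.05. MAGEA10 was at 30.7 ± 4.15 against 26.6 ± 14.8, MAGEC2 at 52.8 ± 2.47 against 56.4 ± 11.1 and MAGEA4 at 60.7 ± 14.4 against 61.2 ± 17.8 CPM. For MAGEC2 and MAGEA4 the sign of the difference turned when certain clones were left out. The 18 genes of NF-kB targets and cytokines gave 0 calls by limma and edgeR and 2 by DESeq2 (3 unadjusted), with CSF1 at 15.9 ± 7.02 against 81.1 ± 52.4 CPM, IL11 at 3.03 against 6.21, CXCL6 at 0.593 ± 0.239 against 4.63 ± 5.10 and CXCL1 at 19.4 ± 16.3 against 77.0 ± 68.1. In ALDH-low clones 1, 3 and 8, CXCL6 had 10.52, 1.77 and 1.6 CPM and CXCL1 150.28, 15.75 and 65.04. Without ALDH-low clone 1 their changes went from -1.46 to -0.76 and from -1.71 to -0.99 log2 units, and CSF1 passed without ALDH-low clone 3 (adjusted p = 0.0278). Their median was 0.29 and their mean 0.01 log2 units, while camera's direction was downward (adjusted p = 0.996).

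Of 22 NRF2 targets 1 fell and 21 did not pass by limma (11 unadjusted), and adjusted over the list alone 3 fell and 1 rose. Over all genes edgeR passed 2 of them and DESeq2 5. FTL, the ferritin light chain, fell from 1041 ± 198 to 497 ± 70.4 CPM (-1.06 log2 units, adjusted p = 0.0427), a call lost when any clone other than ALDH-high clone 1 was left out (adjusted p up to 0.168). With all clones kept it was also lost without a filter, with a filter at 5 CPM, with eBayes without trend (up to 0.0596) and with neighbours subtracted (0.074). FTH1, its heavy chain, was at 296 ± 33.3 against 794 ± 270 CPM (adjusted p = 0.0553). AKR1C1 had 1 read against 1157, a ratio of 1140 (interval 205 to 45200), with 29.48, 1.49 and 15.28 CPM in ALDH-low clones 1, 3 and 8. With all clones kept it did not pass by limma (adjusted p = 0.0812) but passed by edgeR (adjusted p = 0.0383). The change of AKR1C1 went from -3.405 to -2.65 log2 units without ALDH-low clone 1 (adjusted p = 0.201), and to -4.46 without ALDH-low clone 3, where it passed (adjusted p = 0.0035). TXNRD1 stood at 781 against 449 CPM. Of 9 Wnt targets 1 rose, DKK1, and NKD2 joined it over the list alone at 3.73 against 1.56 CPM, with LEF1 at 7.07 against 4.86 and BAMBI at 0.88 against 1.68. The 13 Notch genes gave 0 calls by limma and edgeR and 3 by DESeq2 (4 unadjusted), and over the list alone HES1 rose at 12.7 against 4.06 CPM and DLL1 fell at 0.717 against 2.84, with NRARP at 3.34 against 0.877 and MAML2 at 9.73 against 5.95. The 6 Hedgehog genes gave 0 calls by all 3 tools and 0 at an unadjusted p under 0.05, with CDON, GLI3, SHH and GAS1 all under 6 CPM in both groups.

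The 25 genes of the integrated stress and unfolded protein responses gave 0 calls by limma and edgeR and 3 by DESeq2 (6 unadjusted), with the chaperone HSP90B1 at 1467 against 931 CPM, MANF at 160 against 102, PDIA4 at 325 against 238 and CEBPB at 113 against 163. The 17 heat shock genes gave 0 calls by all 3 tools (1 unadjusted), with HSPA4L at 15.4 against 9.70, HSPA1B at 26.5 against 18.1, BAG3 at 96.6 against 80.6 and HSPH1 at 150 against 119 CPM. The 19 p53 targets gave 0 calls by limma and edgeR and 2 by DESeq2 (5 unadjusted), and over the list alone 1 rose and 2 fell, with MDM2 at 93.8 against 61.5, TNFRSF10B at 24.9 against 43.3, FAS at 8.34 against 13.9 and XPC at 9.35 against 6.06 CPM. Their median and mean were both 0.03 log2 units while camera's direction was downward (adjusted p = 0.996). The 25 immediate early genes gave 0 calls by limma and edgeR and 5 by DESeq2 (11 unadjusted), and over the list alone 1 rose and 2 fell, with DUSP6 at 71.2 against 26.8, FOSL2 at 61.0 against 126, KLF6 at 121 against 184 and JUNB at 93 against 53 CPM.

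The 30 G2/M genes gave 0 calls by all 3 tools (3 unadjusted), with CDK1 at 232 against 173, DLGAP5 at 64.3 against 86.5, CCNB2 at 91.5 against 135 and NUSAP1 at 50.4 against 72.2 CPM. The 43 oxidative phosphorylation genes gave 0 calls by limma and edgeR and 1 by DESeq2 (3 unadjusted), with COX8A at 550 against 873, ATP5J at 909 against 1164, ATP5O at 252 against 314 and NDUFB10 at 337 against 268 CPM. The 77 ribosomal protein genes gave 0 calls by limma and edgeR and 4 by DESeq2 (6 unadjusted), with RPL14 at 212 against 129, RPL29 at 209 against 132 and RPL15 at 2002 against 1283 CPM, all 3 on chromosome 3, and RPS3 at 1584 against 900. The 8 neuronal genes gave 0 calls by all 3 tools (1 unadjusted), with SNAP25 at 13.8 against 5.66, SYP at 8.24 against 4.86, ENO2 at 8.56 against 19.1 and UCHL1 at 183 against 132 CPM. Markers of other cell types were sparse. CD68 was the only leukocyte gene tested, at 112 ± 24.4 against 74.7 ± 15.8 CPM (adjusted p = 0.2), and as a single gene it passed over the list alone. The endothelial genes EGFL7 and TIE1 were at 5.34 against 4.51 and 3.35 against 2.33 CPM, the fibroblast gene FBLN1 was at 6.11 against 5.85, and THY1 passed over the fibroblast list alone. None of the 13 genes on the hepatocyte list was tested. Camera gave adjusted p of 0.0613 to 0.996 for the 19 lists it did not call, and the 8 lists with fewer than 5 tested members were not put to it.

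Wild type was set beside the clones to ask where the control culture lies. At the called genes it lay nearer to the ALDH-high mean for 126 of 170 genes (74.1%, exact 95% interval 66.9 to 80.5%), 63 of 82 that rose and 63 of 88 that fell. Over all tested genes the share was 56.8%. The interval counts the called genes as independent draws. They all come from 1 wild-type library, so the interval does not cover variation between cultures. Wild type had 37.85 CPM of ALDH1A1, 68.3 of EPHA7, 35.13 of HAPLN1 and 51.92 of EDIL3. For genes lower in ALDH-high clones, it had 3.08 CPM of CTB-60B18.15, 4.76 of PTPRK, 0.72 of PTPRD and 1.24 of TENM2. Of the 170 genes, wild type was within the ALDH-high range for 54, within the ALDH-low range for 10 and outside all 6 clones for 23. Among all 12705 tested genes these numbers were 4071, 3598 and 6097. Across the 12705 tested genes, which are not independent replicates, its log2 values correlated with ALDH-high clone 1 at r = 0.961, with clones 6 and 10 at 0.929 and 0.923, and with the ALDH-low clones at 0.911 to 0.921. ALDH-high clones 6 and 10 correlated more closely with every ALDH-low clone (0.949 to 0.957) than with wild type.

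Interferon-stimulated genes stood higher in wild type than in the clones by a median of 1.77 log2 units, at percentile 100 of 10000 matched random lists, and 16 of 23 were above every clone. IFIT1, IFIT2 and IFIT3, antiviral RNA-binding proteins, had 31.45, 49.08 and 31.37 CPM in wild type against clone means of 2.35 ± 1.54, 4.02 ± 3.77 and 2.58 ± 1.94 (n = 6). MMP1, an interstitial collagenase, had 25.14 CPM against 0.94 ± 0.76, KRT15 54.03 against 6.54 ± 3.58 and ARG2, a mitochondrial arginase, 62.79 against 7.59 ± 3.88. GATSL3 and TM4SF1-AS1 had 24.3 and 24.34 CPM against 1.44 ± 0.71 and 2.61 ± 0.89. G1/S genes stood lower by 0.99 log2 units (28 of 30 below every clone) and histone genes lower by 0.97 (33 of 35 below every clone), both at percentile 0 of the matched random lists. MYBL2, a transcription factor of the cell cycle, had 15.59 CPM against 122.8 ± 49.1 in the clones. RNU5D-1 and RNU5A-1, both U5 spliceosomal RNA genes, had 6.31 and 1.04 CPM against 75.6 ± 14.5 and 19.9 ± 7.08. ZDHHC16, SNRNP25, THOP1, CTD-2302E22.3 and RP11-354M1.3 were the other genes farthest below, at 8.47 to 21.62 CPM. Genes of HLA class I presentation, ribosomal proteins and immediate early genes stood higher by 0.47, 0.39 and 0.42 log2 units, each at percentile 100, and neuronal genes by 0.90. For immediate early genes ALDH-high clone 6 lay above wild type, at 0.44. The highest clone lay at 0.29 for ribosomal proteins and 0.64 for neuronal genes (ALDH-high clone 1), and at 0.2 for HLA class I (ALDH-low clone 1). The percentiles draw genes as independent, so they do not measure the spread between libraries. At least 1 log2 unit outside all clones, 148 genes were above and 84 below in wild type, and no test was made of them.

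**Figure D4:**
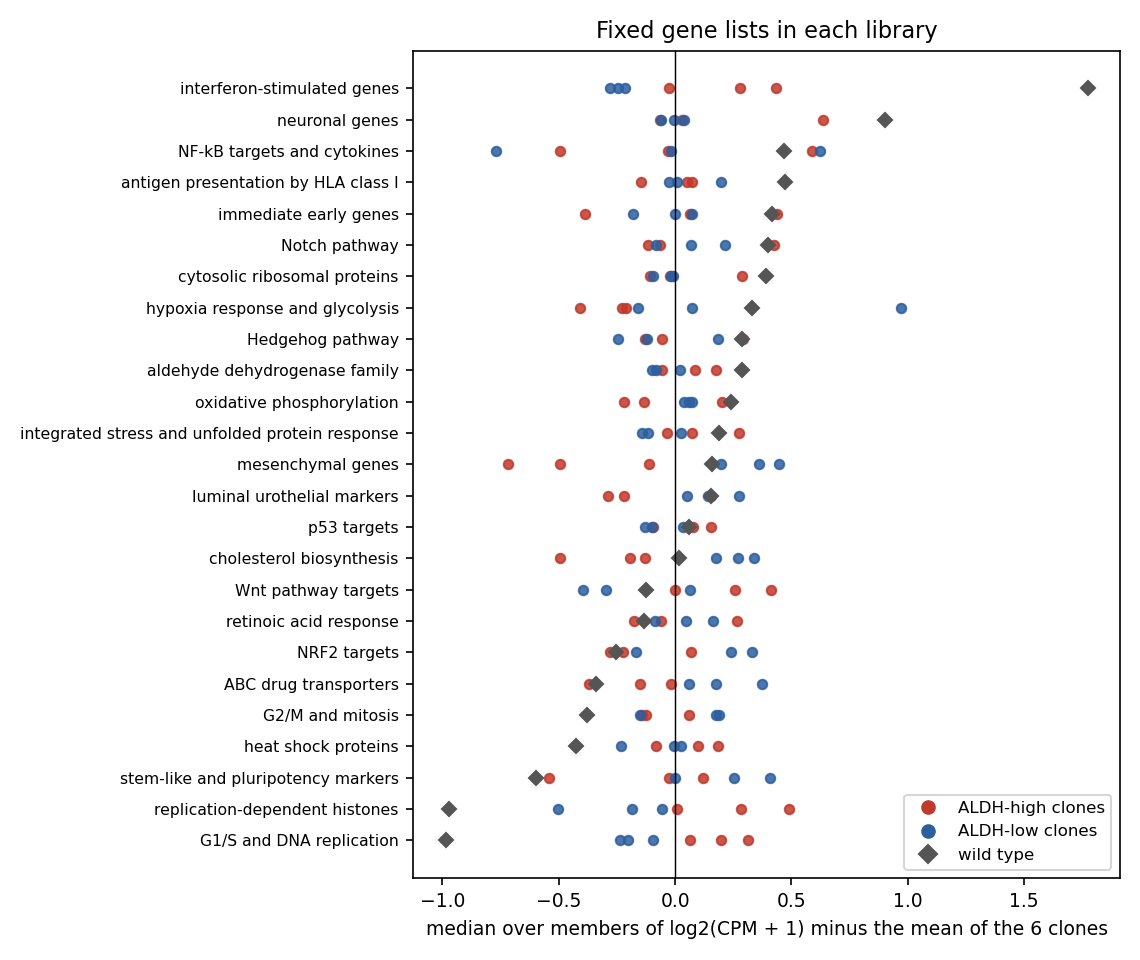
Median over the members of each of 25 lists of log2(CPM + 1) minus the mean of the 6 clones, with 1 point per clone (red ALDH-high, blue ALDH-low) and a diamond for wild type. Wild type lies at 1.77 for interferon-stimulated genes and at -0.99 for G1/S genes, and ALDH-low clone 1 lies at 0.97 for hypoxia response and glycolysis.

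Single clones differed from all other libraries by at least 1 log2 unit above in 8 to 30 genes and below in 0 to 52 genes. ALDH-high clone 10 had 45.52 CPM of MMP9, a gelatinase, against a mean of 5.08 ± 3.89 in the other 6 libraries, and 2.08 CPM of PTPLA against 18.17 ± 7.66. ALDH-low clone 1 had 106.8 CPM of SLC16A3, a lactate transporter, against 15.1 ± 7.89. ALDH-low clone 3 had 35.79 CPM of the syndecan gene SDC2 against 1.04 ± 0.75, 0.04 CPM of ZNF492 against 12.44 ± 3.12, 0 of ZNF90 against 6.98 ± 1.07 and 3.22 of C15orf48 against 104 ± 70.3. ALDH-low clone 8 had 0.08 CPM of SMOC1 against 30.8 ± 19.7, 33.92 of the collagen gene COL6A1 against 3.61 ± 2.08 and 0.68 of GHDC against 8.65 ± 1.72. Further genes that stood out, RNU1-2 and POLR2J2 in ALDH-high clone 1, CBWD1 and MIR3188 in clone 6, HIST2H3C and HIST2H2AA3 in clone 10, BOLA2 and BOLA2B with RP11-231C14.3 in ALDH-low clone 1 and H2BFS in clone 8, belong to families with close copies or share values with another entry, so their reads cannot be assigned with certainty.

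Along the chromosomes, in the gene order of GENCODE release 29 (GRCh38), the differences between clone groups were not spread evenly. The median difference exceeded 0.25 log2 units in either direction in 45 of 241 windows of 50 genes. The window from GCA to AC016739.2 on chromosome 2 had a median of -0.71, with 8% of its genes higher in ALDH-high clones. Windows from CLPB to GAB2 on chromosome 11, SRGAP1 to RP11-613M5.2 on chromosome 12 and TMEM42 to QARS on chromosome 3 had medians of 0.51, 0.47 and 0.46. The window from PTPN3 to TTLL11 on chromosome 9 had -0.48, and 3 windows on chromosome 13 had -0.43 to -0.46. In the chromosome 2 window the ALDH-low clones stood 0.42, 0.95 and 0.54 log2 units above wild type, and the ALDH-high clones between -0.16 and 0.04. Over whole chromosomes the medians ran from -0.34 on chromosome 13 to 0.27 on chromosome 12. With the neighbours' medians subtracted, GRIK2 rose by 4.14 (limma adjusted p = 0.00173) and ALDH1A1 by 5.92 log2 units (adjusted p = 0.00193). The neighbours themselves differed by only 0.06 and -0.24 log2 units, so the subtraction could remove little from either change.

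**Figure D5:**
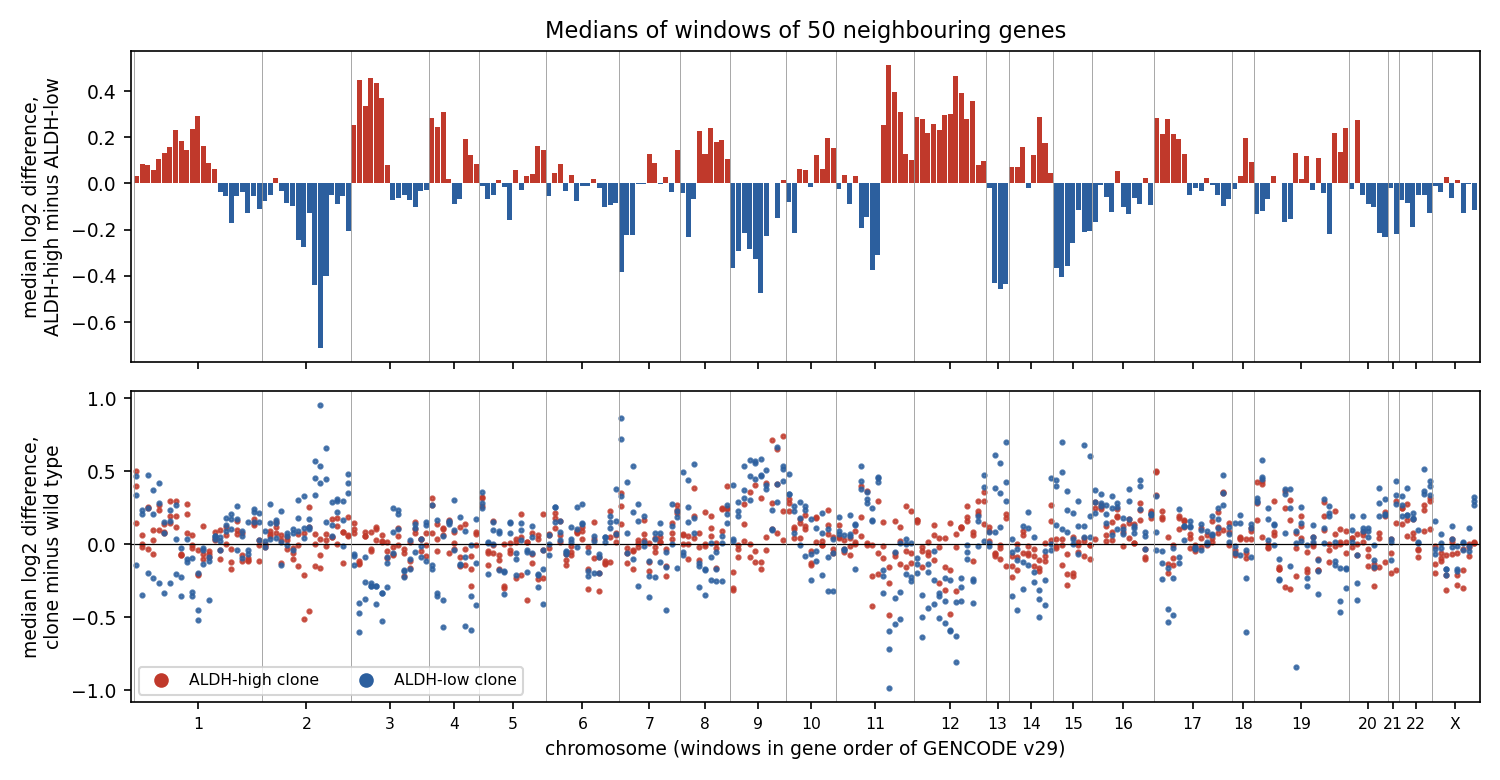
Top, the median log2 difference (ALDH-high minus ALDH-low) of each of 241 windows of 50 neighbouring genes in chromosome order, as bars from 0. Bottom, the median log2 difference of each clone from wild type in the same windows, where the 3 blue ALDH-low points lie at 0.42 to 0.95 in the chromosome 2 window with the lowest bar (-0.71).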

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

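The fits with edgeR and DESeq2, with 1 gene per set of identical values and with neighbour medians subtracted were chosen after seeing the data. GRIK2 rose in all 19 alternatives without subtraction of neighbours, by 2.19 to 10.3 log2 units with adjusted p from 7e-14 to 0.0147. The counts of 82 higher and 88 lower genes stayed within 1.5 times under 10 of the settings that kept all clones. Among these, subtraction of neighbours gave 60 and 60, and only 101 of the 165 genes called before it (1 gene per set of identical values) were among these 120. They were 43 and 43 with a filter at 5 CPM (10311 genes tested), 328 and 372 with library weights, and 466 and 538 with DESeq2. With edgeR 54 were higher, and the 75 lower stayed within 1.5 times. The cause was not tested for library weights, edgeR and DESeq2. Leaving out each clone gave 20 to 93 higher and 14 to 80 lower genes, on fewer samples. The number of lists called by camera was 11 with library weights and 7 to 11 without each clone (11 without ALDH-high clone 1), against 6, and the cause was not tested.

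Of the 38 genes under the naming rule that passed, 17 passed under every alternative, subtraction of neighbours included: GRIK2, ALDH1A1, EPHA7, HAPLN1, EDIL3, RP11-151D14.1, LPHN3, PTPRM, PCSK1N, DKK1, BDKRB1, PTPRK, PTPRD, DPP7, SMIM10, SLC35D2 and ZEB2. None of the 38 turned direction. Of the 37 besides GRIK2, the calls lost were 11, 15 and 17 without ALDH-high clones 1, 6 and 10, and 18, 4 and 19 without ALDH-low clones 1, 3 and 8, with adjusted p up to 0.174 (SNAI2). With all clones kept, 8 were lost with a pseudocount of 5, 7 with edgeR, 1 with robust estimation and 5 each without a filter, with a filter at 5 CPM (where 30 of the 37 were tested) and with eBayes without trend. With neighbours subtracted TNC, DGKI, SLC43A3, MCM4, SNAI2 and FTL were lost (adjusted p = 0.0573 to 0.074). Without 1 clone some genes that had not passed did so: ITGA6 and THY1 without ALDH-high clone 6 (adjusted p = 0.0377 and 0.0013), GRID1, HES1 and COX8A without ALDH-high clone 1 (0.0449, 0.048 and 0.0458), FTH1 without ALDH-low clone 1 (0.0245), and AKR1C1, CSF1 and HK1 without ALDH-low clone 3 (0.0035, 0.0278 and 0.0296). Signs turned in 6 genes that had not passed. OCLN (0.08) was at -0.17 with library weights and -0.155 to 0.266 without each clone. CLDN1 (-0.15) was at 0.056 with library weights and -0.839 to 0.466 without each clone. MAGEA4 (-0.002) was at 0.005 with quantile normalization and -0.16 to 0.222 without each clone. MAGEC2 (-0.08), TIE1 (0.36) and FBLN1 (0.08) ranged over -0.16 to 0.075, -0.121 to 0.881 and -0.057 to 0.284 without each clone. Wild type lay nearer to the ALDH-high mean for 123 and 129 of the 170 genes with pseudocounts of 0.1 and 5. Scaling moved the median of all genes to between -0.014 and 0.014 log2 units. No listed alternative was left out. No paired analysis was possible because clone numbers name separate clones and only number 1 occurs in both groups. At this depth a count of 0 leaves up to 0.123 CPM open.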

Other observations

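The tests on how many lists other splits call, on copy number, on wild type as a mix and on wild type across all genes were chosen only after the result was seen, as were the neighbour pairs and zinc finger counts. Called genes lay next to each other more often than in shuffled orders: 14 neighbouring pairs of the same direction against at most 6, and a median of 1, in 1000 shuffles. Among them were RP11-151D14.1 with ALDH1A1, HAPLN1 with CTD-2269F5.1 and EDIL3, TNC with PAPPA, FTL with GYS1, and NTF6G, CTB-60B18.17 and CTB-60B18.15. Zinc finger genes with symbols beginning ZNF made up 7 of the 82 genes that rose (8.5%) and 0 of the 88 that fell, against 368 of 12705 tested (2.9%), a count made because such genes had been seen among the rises and given without a test. On chromosome 19 ZNF813 lay between TPM3P9 and ZNF331, and the median change of all ZNF genes was 0.16 log2 units.

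The 6 clones can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 170 genes and the highest other split 1, so 1 of 10 splits gave as many. For lists the real split gave 6, and 9 of 10 splits gave as many or more, the real one included. The highest other gave 11, in the split that put ALDH-high clone 1 with ALDH-low clones 3 and 8. The number of called lists thus does not set the real split apart from the others.

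Differences between the clone groups lay in runs along chromosomes: the SD of the window medians was 0.192, against at most 0.076 in shuffled orders. Genes that share the same reads are argued against as the source, since 0.192 was reached with 1 gene per set of identical values, and so is GC content at the transcripts' start, since the SD stayed at 0.191 (at most 0.074 in shuffled orders) once its trend was removed. DNA copy number that differs between clones cannot be told apart from chromatin domains that change together or other regional causes: the SD of 0.192 only measures the runs themselves, and DNA was not measured. The 54 genes changed by over 2 log2 units included GRIK2 and ALDH1A1. With neighbours subtracted their median change went from 2.62 to 2.55 (bootstrap interval 2.39 to 2.89), and 47 still passed. The largest window median was -0.71 log2 units, so subtraction could remove little from changes of this size. Shifts shared by 25 neighbours on each side were thus too small to make up these changes. Such a median misses clusters of a few genes, and ALDH1A1 and HAPLN1 each lay beside a gene that also rose. Causes that act on such short clusters stay open. For the 46 genes under 1.2 log2 units the runs as the cause stay open. Their median change went from 0.95 to 0.77, lower by 18.6% (bootstrap interval 9.7 to 31.9%, on both sides of the 25% set in advance). That interval counts genes as independent, though genes within a run move together. For 39 of the 46 the neighbours moved the same way as the gene, and 15 still passed. Median SE was 0.156 before and 0.147 after, so it did not grow.

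Wild type lay near the ALDH-high clones at genes that were nearly on or off between the groups. A mix of ALDH-high-like and ALDH-low-like cells in the wild-type culture is a candidate explanation: the ALDH-high-like share had a median of 0.82 from 35 genes high in ALDH-high clones (quartiles 0.53 to 0.98) and 0.89 from 31 genes high in ALDH-low clones (0.8 to 0.96), ranges that overlap. Of these genes 8 and 6 lay beyond a share of 1, and genes of 1 library are not replicates. ALDH-high-like cells alone could also give overlapping ranges, so the overlap does not decide for a mix. A mix of cells like these 6 clones would give levels within their range. Wild type lay outside that range for 23 of 170 called and 6097 of 12705 tested genes. It was above every clone for 16 of 23 interferon-stimulated genes and below every clone for 28 of 30 G1/S genes. Wild type being nearer to ALDH-high clones across all genes cannot be told apart from a mix: the called genes exceeded all genes by 17.3 points, but the lower bound ran down to 8.0 points over the pseudocounts, with 10 set as the limit after the values were seen. That bound also counts genes of 1 library as independent, so it is narrower than the real uncertainty. A biological difference between sorted clones and the unsorted culture is untested, since the wild type is a single library.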
